A study of Mus musculus with 14 samples.

How the data were processed

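RNA was measured by sequencing of polyadenylated RNA from colon tissue of ICR mice in 14 libraries, built with a TruSeq kit per the labels' protocols. Per the submitters' processing notes, reads were handled with Trimmomatic, HISAT2, StringTie and DESeq2 on the mouse build mm10, with no versions given and no role stated for each tool. The deposited table listed 18536 genes by NCBI gene identifier and symbol, and every gene had a count of at least 1 in every library. A gene silent in even a single library was therefore not analysed here. Ifnb1 and Il6 were not among the genes tested, being either absent from the deposited table or removed by the filter described below.

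The table held read counts per gene, which the authors deposited as estimated counts that were already whole numbers, so rounding them left each value as it was. It also held TPM values (length-scaled transcript shares) computed by the authors, used here only as an alternative unit. Columns of fold changes and of p-values, unadjusted and adjusted by the Benjamini-Hochberg method, were deposited by the authors for a pair of comparisons as well. The column headed G4/G2 was read as 5-HTP+KC84 against 5-HTP, because a DESeq2 fit of those groups gave the same log2 fold changes to within 9.5e-10. The authors' values were used only where they are named. No column of sample values was left unused.

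Groups and replicate numbers came from the sample labels. No 2 libraries of a group agreed within sampling noise, the smallest chi-square per gene being 60.1, so each counted as 1 replicate. Library totals ran from 44474548 to 60099210 counts. At that depth, the spread between libraries and not counting error limited precision for all but the lowest genes.

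Genes were tested with edgeR 4.0.16 in R 4.3.3, using TMM factors, the filterByExpr filter by group, a robust quasi-likelihood fit of all 14 libraries with group as the only term, and quasi-likelihood F-tests for the 3 comparisons. The filter left 17900 genes. A gene was called changed at a Benjamini-Hochberg adjusted p below 0.05. Values per library are CPM (counts scaled to a common library size) on TMM-scaled libraries, as mean ± SD, and the standard error (SE) of a log2 fold change was taken from its F statistic.

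Gene lists fixed before the data were examined numbered 43, and 41 had at least 5 tested members. Those not tested were type I and III interferons with their receptors, and pancreas and small intestine. They covered serotonin handling, interferon and antigen presentation, barrier and transport, stress responses, the clock and metabolism, and the epithelial, immune, muscle, nerve and stromal cells that a piece of colon could hold. Each was tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over lists within a comparison. The alternatives were camera with an estimated correlation, fry, and an exact two-sided permutation test of the list score, which is the mean centred log2 CPM of a list's members in a library. With 126 ways to divide the libraries, its p cannot fall below 0.00794, so a lone list cannot pass the adjustment over 41 lists. A list's member counts are given over all tested genes and adjusted over the list alone.

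The genes named in the text followed a rule written before the data were examined. It took the 8 largest rises and the 8 largest falls among called genes with a mean log2 CPM of at least 0, up to 3 members with the smallest p from each described list, and a fixed set of 24 genes of serotonin, interferon, dendritic cell, barrier and transport biology for both 5-HTP comparisons, of which 22 were tested. Which lists to describe was chosen after their results were seen, so that every called list could be named, and posterior Hox genes were described as a sign of position along the colon. Predicted genes and genes without a symbol were only counted, and some named genes were left out for length. Gene identifiers matched the RefSeq annotation of GRCm38.p6, of which mm10 is the browser name, for 18494 of 18536 genes, and coordinates are from that annotation.

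Alternatives included DESeq2 1.42.0, voom of limma with sample quality weights, other scaling factors and filters, TPM as unit, fits of only the groups compared, the replicate number as a block, 1 surrogate variable from sva 3.50.0, and leaving out each library. The fit without both replicate 5 libraries and the permutation of list scores were added after the data had been seen. On counts simulated for the 5-HTP and naive groups over 17900 genes, edgeR recovered 49% of genes changed 2-fold and 89% of those changed 4-fold, with 4 false calls among 106, and DESeq2 64% and 92% with 20 false calls among 143. On counts simulated for the 5-HTP+KC84 and 5-HTP groups, edgeR recovered 57% and 92% with 5 false calls among 115, and DESeq2 76% and 98% with 47 false calls among 181. On counts simulated for the 5-HTP+KC84 and naive groups, edgeR recovered 61% and 89% with 4 false calls among 114, and DESeq2 82% and 92% with 33 false calls among 173. In the same 3 simulations, voom made 6 false calls among 105, 6 among 113 and 6 among 116. Each gene was drawn independently, with no structure shared between genes of a library and no poor library. The simulated false call rates may therefore not hold for the real libraries.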

Results

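Colon tissue of ICR mice, an outbred stock, was profiled in 14 RNA sequencing libraries of 3 groups. The naive group (n = 5) received vehicle in place of both treatments, the 5-HTP group (n = 5) received 5-hydroxytryptophan, the direct precursor of serotonin, and the 5-HTP+KC84 group (n = 4) received 5-HTP and KC84, a strain of the gut bacterium Bifidobacterium stercoris. KC84 or its vehicle was given by mouth each day for 14 days, and 5-HTP was injected into the abdominal cavity daily for 7 days from day 8. The study's title places the model among diarrhoea-predominant irritable bowel syndrome models and names serotonin pathways and interferon beta from dendritic cells as its subjects. Libraries held 44474548 to 60099210 counts. The labels do not tie each library to its own animal, so p-values measure only the spread between these libraries, which may be partly technical. Naive replicate 5 and 5-HTP replicate 5 stood apart from the rest: across genes, which are not independent replicates, their deviation from their group mean correlated with transcript length at -0.43 and -0.46, against -0.18 to 0.31 in the other 12. Deviations cancel out within a group, so the positive values of their group mates arise in part from these libraries.

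The comparison of 5-HTP with naive colon asked what the serotonin precursor changed. Bhlha15 (Mist1; gene 17341, chromosome 5, 144190286 to 144194441), a transcription factor of secretory cells, rose 4.24-fold with 5-HTP, from 4.56 ± 1.13 to 19.3 ± 4.72 CPM (SD, n = 5 each), and was above every naive library in 5 of 5. Pheta1 (gene 231717, chromosome 5, 121848997 to 121854604), which encodes an endosomal trafficking protein, fell 1.8-fold, from 44.6 ± 5.01 to 24.8 ± 3.86 CPM, and was below every naive library in 5 of 5. The edgeR test called these 2 genes of 17900, Bhlha15 at an adjusted p = 0.0083 (log2 fold change 2.08, SE 0.24) and Pheta1 at 0.042 (-0.84, SE 0.12). An unadjusted p under 0.05 was reached by 2374 genes, where 895 would be reached by chance, and DESeq2 called 545 genes, voom with quality weights 868 and the authors' deposited p-values 380. The edgeR count was 1 without naive replicate 1 or 5 or 5-HTP replicate 3 or 4, 0 without naive replicate 2 or 3, 6 without 5-HTP replicate 1, 242 without naive replicate 4 and 32 without both replicate 5 libraries. The Bhlha15 call ended without naive replicate 2 or 3, at an adjusted p of at most 0.063, and the Pheta1 call ended in 9 of the 14 fits that left out 1 library and with upper-quartile factors or TPM.

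Slc6a4 (gene 15567, chromosome 11, 76998597 to 77032343), the transporter that takes serotonin back into cells, averaged 8.26 ± 3.76 CPM with 5-HTP and 17.9 ± 4.99 CPM in naive colon, a log2 difference of -1.11 (SE 0.29, adjusted p = 0.13). The authors' deposited table gives Slc6a4 a fold of -2.18 with an adjusted p of 0.031, and DESeq2 on all 3 groups gave 0.012. By edgeR with 1 library left out, its adjusted p ran from 0.039, without naive replicate 4, to 0.27. Ddc, which converts 5-HTP to serotonin, averaged 74.3 ± 18.1 against 110 ± 20.3 CPM (log2 -0.56, SE 0.16, adjusted p = 0.16). Tph1, the rate-limiting enzyme of serotonin synthesis in the gut, differed by -0.04 (SE 0.2), Maoa, which breaks serotonin down, by 0.24 (SE 0.11), and the receptors Htr3a and Htr4 by 0.15 (SE 0.17) and 0.03 (SE 0.28). Of the 13 tested genes of serotonin synthesis, transport and breakdown, edgeR called 0 over all genes and 2, both lower, adjusted over the list alone, with 5 at an unadjusted p under 0.05. DESeq2 called 1 and voom 3. The list as a whole had an adjusted p = 0.861, and the 6 tested serotonin receptor genes had 0.324 by camera.

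**Figure D1:**
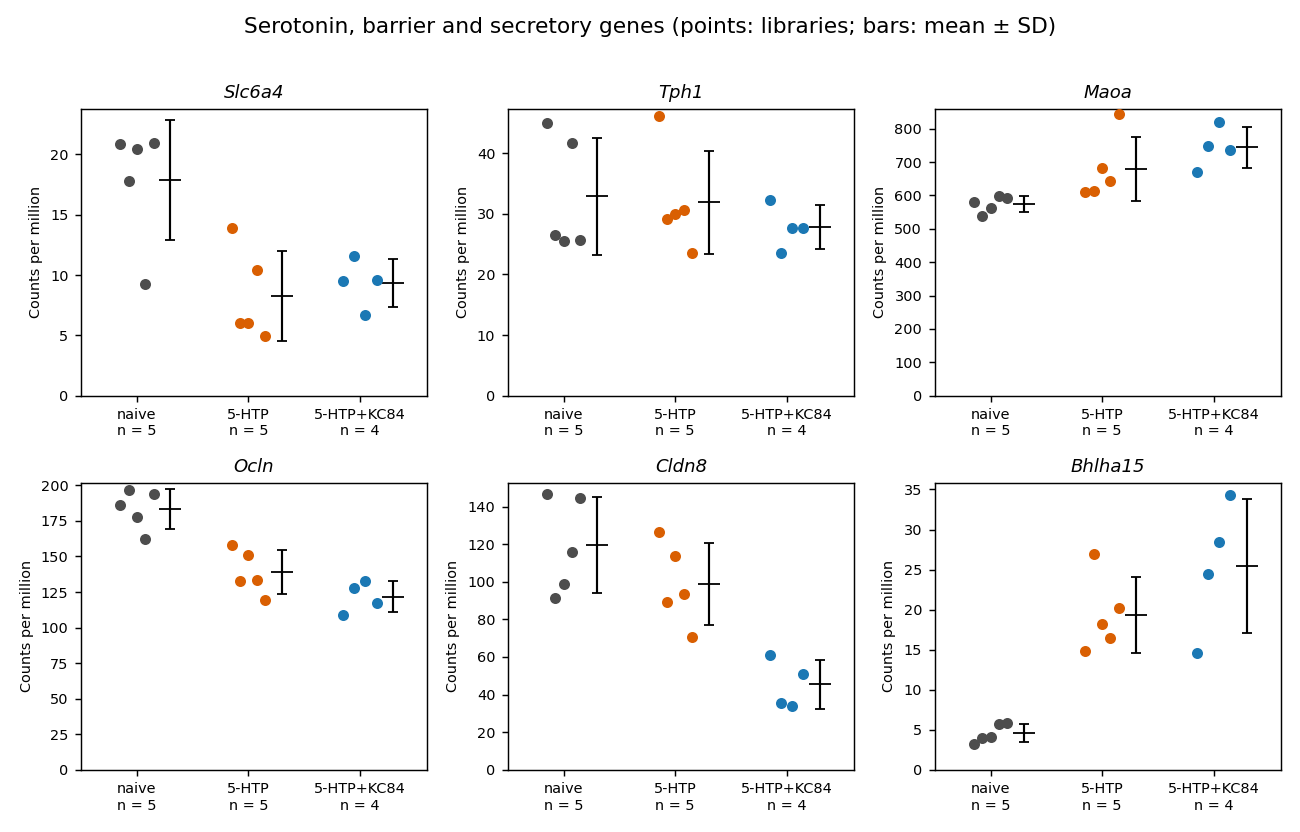
CPM of 6 genes in each library of the naive (n = 5), 5-HTP (n = 5) and 5-HTP+KC84 (n = 4) groups, with the mean ± SD beside the points. Bhlha15 lies between 3.24 and 5.78 CPM in the naive libraries and between 14.5 and 34.3 CPM in all others, and Slc6a4 of naive replicate 4 lies at 9.25 CPM, below the other naive libraries.

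Stress-response and gut wall lists stood higher with 5-HTP by camera. All 12 heat shock genes were positive (median log2 0.43, adjusted p = 1.44e-06), with adjusted p = 0.56 with an estimated correlation. Hspa1a averaged 184 ± 70.3 against 55 ± 28.5 CPM (log2 1.74, SE 0.39, adjusted p = 0.1). Hspa1a and its near-identical neighbour Hspa1b can share reads, so their separate values are uncertain. Of the 16 genes of endoplasmic reticulum and integrated stress, 15 were positive (median 0.47, adjusted p = 3.37e-05), with adjusted p = 0.56 with an estimated correlation, among them the chaperone gene Dnajb9 at 122 ± 37.6 against 64.5 ± 13.3 CPM (adjusted p = 0.089). By edgeR, 0 members of either list passed over all genes, 5 and 3 passed adjusted over the list alone, 6 and 9 had an unadjusted p under 0.05, and DESeq2 called 2 in each. Smooth muscle genes (20 of 20 positive, median 0.44) and enteric neuron genes (18 of 18, median 0.29) were higher at adjusted p = 0.000126 and 0.000582. With an estimated correlation these became adjusted p = 0.57 and adjusted p = 0.56, and without both replicate 5 libraries the medians were 0.14 and 0.16, at adjusted p = 0.0645 and 0.0107. Posterior Hox genes, which mark position along the colon, were negative in 6 of 9 (median -0.12, camera adjusted p = 0.0726, or -0.36 and 0.0107 without both replicate 5 libraries; permutation p = 0.0238, or 0.23 adjusted), with 0 called by edgeR, 2 lower adjusted over the list alone, 3 at an unadjusted p under 0.05, 2 lower by DESeq2 and 1 by voom. With an estimated correlation the list had adjusted p = 0.56, and Hoxb13 averaged 113 ± 62.9 against 275 ± 70.1 CPM (log2 -1.28, SE 0.39, adjusted p = 0.17).

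Of 32 interferon-stimulated genes 31 were negative with 5-HTP, with a median log2 of -0.6 (camera adjusted p = 1.09e-07), and of 23 genes of the interferon-gamma response and class I presentation 21 were negative, with a median of -0.43 (9.38e-07). Both had adjusted p = 0.56 with an estimated correlation, and exact permutation p = 0.143 and 0.0794 between the groups. The interferon-stimulated score ran from -0.745 (naive replicate 4) to 1.179 (naive replicate 3) in naive libraries. In 5-HTP libraries it ran from -1.048 to 0.049, so the groups overlapped. Trim30a, a gene induced by interferon, averaged 13.6 ± 2.5 against 32.6 ± 20.7 CPM (adjusted p = 0.13), while Mx1, an antiviral gene, went the other way at 9.5 ± 4.6 against 4.54 ± 1.75 CPM (adjusted p = 0.32). Over all genes edgeR called 0 interferon-stimulated genes, and 0 adjusted over the list alone, with 14 at an unadjusted p under 0.05, 2 by DESeq2 and 5 by voom. In the same libraries the lists of T and NK cells (median -0.47, 16 of 16 negative, adjusted p = 0.000752), B and plasma cells (-0.41, 0.0147), class II presentation (-0.44, 0.00181), macrophages (-0.19, 0.00861) and dendritic cell markers (-0.15, 0.0432) stood lower, each with adjusted p = 0.56 with an estimated correlation except dendritic cell markers, with adjusted p = 0.58. The T and NK cell score of naive replicate 3 stood apart at 1.1, with the other naive libraries at 0.02 to 0.28. 5-HTP libraries ran from -1.025 to 0.372 on that score (exact permutation p = 0.167 between the groups). Without both replicate 5 libraries the median of class II presentation was -0.28, and dendritic cell markers had an adjusted p of 0.127. The dendritic cell genes Itgax, Zbtb46 and Flt3 differed by -0.23 (SE 0.3), 0.05 (SE 0.16) and -0.08 (SE 0.27). Of the 41 lists, 17 were called by camera, 8 higher and 9 lower, and 0 were called with an estimated correlation, by fry or by the permutation test, in which 8 had an unadjusted p under 0.05. The permutation test could hardly call a list here, since its p cannot fall below 0.00794.

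Among barrier and transport genes, Ocln, a tight junction protein, averaged 139 ± 15.6 with 5-HTP and 183 ± 14 CPM in naive colon and was lower in 5 of 5 libraries (log2 -0.4, SE 0.1, adjusted p = 0.11). Of 18 junction genes 15 were negative (median -0.13, adjusted p = 0.0147), with adjusted p = 0.56 with an estimated correlation, and edgeR called 0 over all genes and 3 adjusted over the list alone, with 5 at an unadjusted p under 0.05, 2 by DESeq2 and 4 by voom. Tjp1, Cldn1 and Cldn2 differed by -0.14 (SE 0.23), 0.06 (SE 0.18) and -0.25 (SE 0.14). The gel-forming mucin gene Muc2 averaged 3210 ± 1690 against 1710 ± 1620 CPM, a difference within the spread between libraries (log2 0.91, or 1.67 without naive replicate 4). By edgeR 0 of the 18 clock genes passed, against 3 by DESeq2, 2 by voom and 3 in the authors' deposited p-values, with 3 higher and 1 lower adjusted over the list alone and 7 at an unadjusted p under 0.05. Hlf, Ciart and Dbp were above every naive library in 5 of 5, with Hlf at 9.89 ± 3.3 against 3.47 ± 0.887 CPM (log2 1.51, SE 0.25, adjusted p = 0.065). The water channel gene Aqp8 and the chloride exchanger gene Slc26a3 differed by 0.21 and -0.21 (SE 0.15 each).

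The comparison of 5-HTP+KC84 with 5-HTP asked what the bacterium changed in treated mice. Output and repressor genes of the circadian clock were among those that rose: Ciart 8.01-fold, from 1.19 ± 0.477 to 9.53 ± 1.63 CPM, Dbp 7.11-fold, from 7.57 ± 5.03 to 53.7 ± 12.4 CPM, Tef 4.84-fold, Per3 3.95-fold, Hlf 3.2-fold and Per2 2.42-fold (SD, n = 4 and 5). The activator genes Arntl (Bmal1; gene 11865, chromosome 7, 113178471 to 113314126) and Npas2 fell 3.71-fold and 2.79-fold, Arntl from 60.5 ± 15.8 to 16.3 ± 1.98 CPM. Each of these genes lay outside the range of the 5-HTP group in 4 of 4 libraries with KC84. Beyond this fixed list of 18 clock genes, Cipc, a partner of the clock protein, rose 1.75-fold and Ccdc116 rose 2.55-fold, and Spon2, which encodes a secreted matrix protein, fell 2.63-fold.

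The edgeR test called 17 genes, 13 higher and 4 lower, and 8 of them were clock genes. Arntl had an adjusted p = 0.00065 (log2 -1.89, SE 0.18), Per3 0.001 (1.98, SE 0.21), Ciart 0.001 (log2 3, SE 0.32) and Npas2 0.023 (-1.48, SE 0.23). Of the 18 clock genes, 6 rose and 2 fell over all genes, 12 rose and 5 fell adjusted over the list alone, and the list passed camera at an adjusted p of 1.66e-08, with adjusted p = 0.0038 with an estimated correlation. Fry, which tests movement on balance one way, gave 9.34e-05. An unadjusted p under 0.05 was reached by 964 genes against 895 by chance, and DESeq2 called 64 genes, voom 140 and the authors' deposited p-values 80. The count was 3 without 5-HTP replicate 2 or 4, 11 without 5-HTP replicate 3, 30 without 5-HTP replicate 5, 4 without 5-HTP+KC84 replicate 1 or 3, 5 without 5-HTP+KC84 replicate 2, 10 without 5-HTP+KC84 replicate 4, 5 with only both groups in the fit and 38 without both replicate 5 libraries. Arntl, Ciart and Per3 passed in each of the 14 fits that left out 1 library, while Tef lost the call in 2 of them, Dbp, Hlf, Per2 and Cipc in 5 each, Spon2 in 6, Npas2 in 7 and Ccdc116 in 10. Per2, Npas2, Spon2 and Ccdc116 also lost it on TPM, and Hlf with the replicate number as a block. Collection times were not given in the sources used here.

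**Figure D2:**
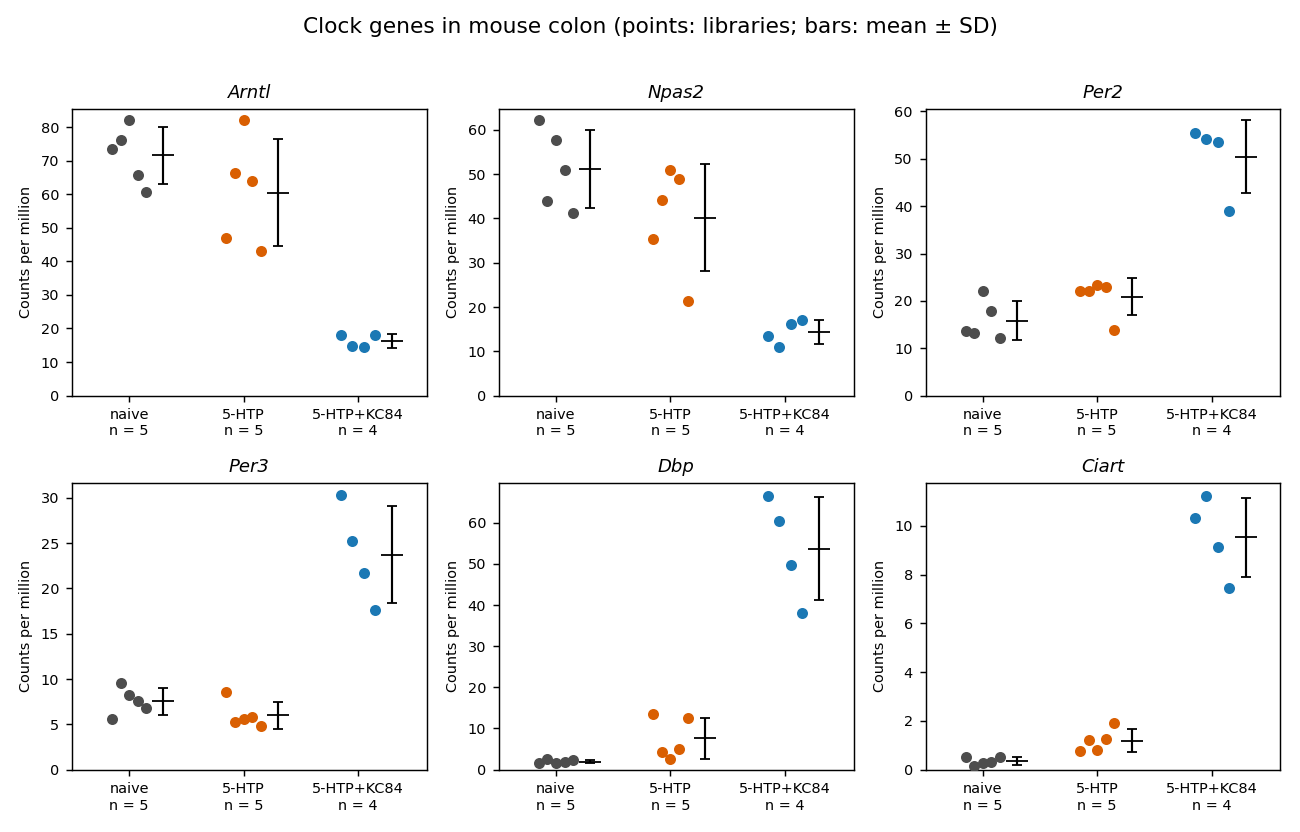
CPM of 6 clock genes in each library of the naive (n = 5), 5-HTP (n = 5) and 5-HTP+KC84 (n = 4) groups, with the mean ± SD beside the points. Arntl lies between 14.5 and 18.1 CPM in the 4 libraries with KC84 and between 43 and 82 CPM in all others, and Dbp lies between 38.2 and 66.4 CPM in those 4 libraries and at no more than 13.4 CPM in all others.

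Interferon-stimulated genes stood higher with KC84 than with 5-HTP alone. All 32 were positive, with a median log2 of 0.69 (adjusted p = 1.45e-18 by camera), with adjusted p = 0.52 with an estimated correlation. The list score averaged 0.37 ± 0.34 with KC84, -0.45 ± 0.47 with 5-HTP and 0.16 ± 0.72 in naive colon, and the first 2 differed at p = 0.0317 in a two-sided exact permutation test (0.43 adjusted over lists). Ifit1, Isg15 and Irf7 averaged 30.9 ± 11.5, 26.1 ± 10 and 142 ± 67.1 CPM with KC84 against 16.1 ± 8.63, 13.9 ± 14.7 and 92.7 ± 52.8 CPM, with Isg15 at log2 0.91, or 1.81 without 5-HTP replicate 5, and Irf7 at 0.61, or 0.25 without 5-HTP+KC84 replicate 3. By edgeR and DESeq2, 0 of the 32 passed, also 0 adjusted over the list alone by edgeR, with 10 at an unadjusted p under 0.05. The authors' deposited p-values call 3 of them higher, among them Herc6 (1.91-fold, adjusted p = 0.019) and Dhx58 (1.83-fold, 0.034). Genes of the interferon-gamma response and class I presentation were positive in 19 of 23 (median 0.21, adjusted p = 0.000538, or 0.0564 without both replicate 5 libraries), with adjusted p = 0.67 with an estimated correlation. Itgax, Zbtb46 and Flt3 differed by 0.11 (SE 0.32), 0.26 (SE 0.17) and 0.09 (SE 0.29), and the dendritic cell marker list had an adjusted p = 0.905, with a median of 0.03 and a mean of -0.03.

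**Figure D3:**
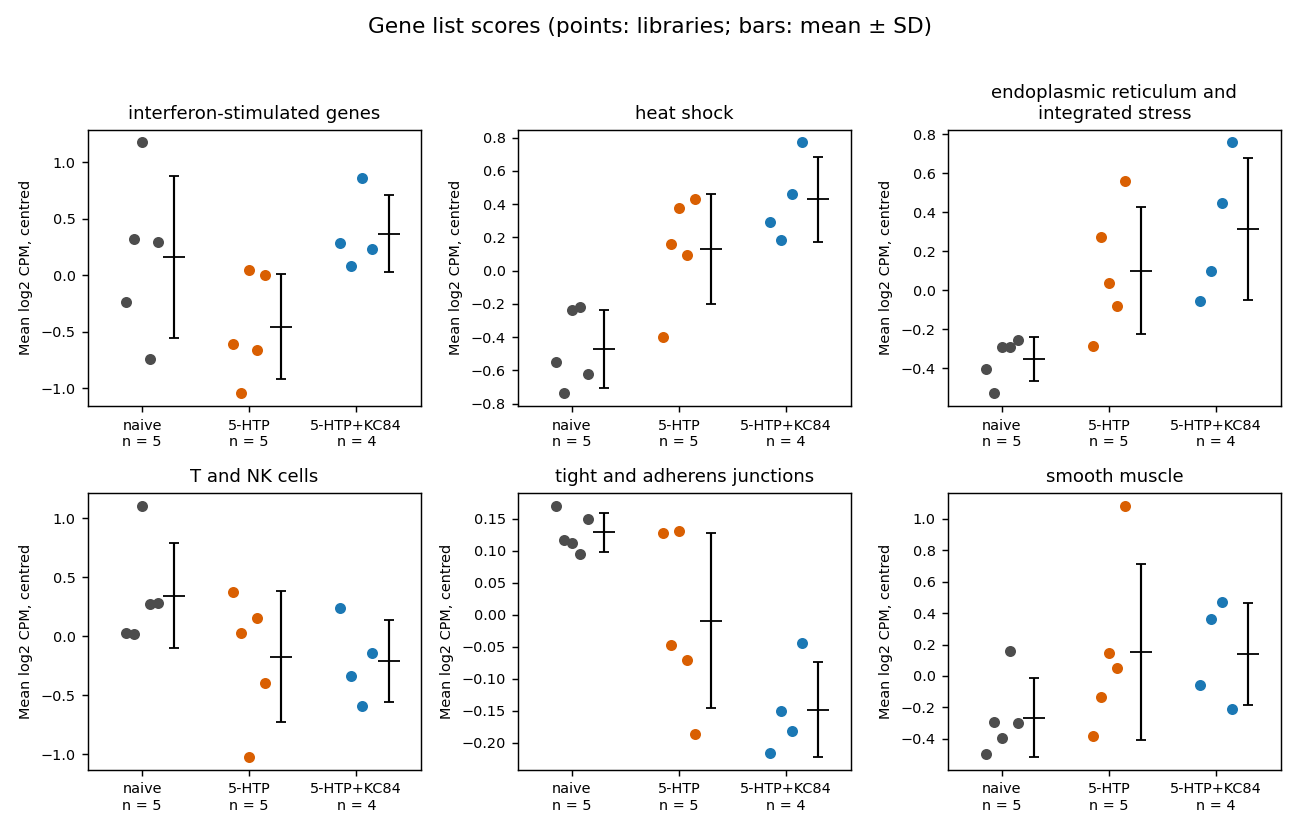
Scores of 6 gene lists, each the mean centred log2 CPM of the list's genes, in each library of the naive (n = 5), 5-HTP (n = 5) and 5-HTP+KC84 (n = 4) groups, with the mean ± SD beside the points. The 5-HTP group has the lowest mean for interferon-stimulated genes, at -0.45, and naive libraries spread from -0.75 to 1.18.

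Other lists moved with KC84 by camera only. Proliferation genes were lower (17 of 20 negative, median -0.35, adjusted p = 1.35e-07), with adjusted p = 0.67 with an estimated correlation, and Bub1 averaged 10.9 ± 2.06 against 15.3 ± 1.68 CPM. By edgeR 0 of them passed. The proliferation score of 5-HTP+KC84 replicate 4, at 0.284, lay above every 5-HTP library (-0.272 to 0.263). The other libraries with KC84 lay at -0.454 to -0.384 (exact permutation p = 0.183 between the groups). Heat shock genes were positive in 12 of 12 (median 0.29, 0.000829), enteric neuron genes in 14 of 18 (0.2, 0.00414) and endoplasmic reticulum stress genes in 14 of 16 (0.14, or 0.28 without both replicate 5 libraries, 0.0185). With an estimated correlation these had adjusted p = 0.67, 0.67 and 0.7. Junction genes were negative in 15 of 18 (median -0.13, 0.0147), with adjusted p = 0.52 with an estimated correlation, and macrophage genes in 11 of 14 (-0.19, 0.0299, or 0.0533 without both replicate 5 libraries), with adjusted p = 0.67 with an estimated correlation. Cldn8, a claudin of the tight junction, averaged 45.4 ± 13.2 with KC84 and 98.8 ± 21.8 CPM with 5-HTP and was lower in 4 of 4 libraries (log2 -1.12, SE 0.22, adjusted p = 0.12). It passed in DESeq2 at 0.00095 and in edgeR without 5-HTP replicate 5 at 0.045. Of the 41 lists 13 were called, 9 higher and 4 lower, against 7 without 5-HTP replicate 1, and 1, the clock list, was called with an estimated correlation. Serotonin genes did not pass: Slc6a4, Tph1, Maoa, Htr3a and Htr4 differed by 0.18 (SE 0.31), -0.2 (SE 0.21), 0.13 (SE 0.11), 0.15 (SE 0.18) and -0.07 (SE 0.3).

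Genes that 5-HTP changed and KC84 moved back were sought as those called in both comparisons with opposite signs. There were 0 by edgeR and 3 by DESeq2, which were BC064078, Gm6212 and Gm8515. With voom there were 4, which were 1700030K09Rik, Smim24, Mlkl and Neurl3, and these 7 were named only after their values were seen. Gm6212 averaged 6.66 ± 5.91 CPM with KC84, a spread close to its mean, and whether an inherited variant sets its level was not tested. At an unadjusted p under 0.05 in both comparisons 91 genes had opposite signs and 100 had the same sign. Across the 17900 genes, which are not independent replicates, the log2 fold changes of the 2 comparisons correlated at -0.082, while simulated unchanged groups that shared the 5-HTP libraries gave -0.457 (-0.721 to -0.046). The covariance was -0.0088 against -0.0365 simulated. With the 5-HTP libraries split between the comparisons, the correlation averaged 0.208 over 20 splits. Slc6a4 averaged 9.33 ± 2 CPM with KC84, 8.26 ± 3.76 with 5-HTP and 17.9 ± 4.99 in naive colon, and Bhlha15 was called above naive in both treated groups.

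The comparison of 5-HTP+KC84 with naive colon covered both treatments together. Since collection times were not given, a difference in time of day between these groups could enter these results too. Whether it did so beyond the clock genes was not tested. Among clock genes, Dbp rose 27.2-fold, from 1.97 ± 0.418 to 53.7 ± 12.4 CPM, Ciart 26.9-fold and Hlf 9.12-fold, while Arntl fell 4.39-fold (SD, n = 4 and 5). The heat shock gene Hspa1a rose 5.01-fold to 276 ± 130 CPM, and the endoplasmic reticulum stress genes Herpud1 and Chac1, a glutathione-degrading enzyme, rose 1.95-fold to 253 ± 64.5 CPM and 9.28-fold to 6.31 ± 6.36 CPM, although Chac1 went from log2 3.21 to 2.3 without 5-HTP+KC84 replicate 4. The tight junction genes Cldn8, Cldn12 and Ocln fell, Cldn8 2.63-fold to 45.4 ± 13.2 from 120 ± 25.6 CPM, Cldn12 1.55-fold and Ocln 1.51-fold to 122 ± 10.8 from 183 ± 14 CPM. Ddc fell 1.84-fold, and Maoa averaged 744 ± 61 against 575 ± 23.7 CPM (adjusted p = 0.072).

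The edgeR test called 736 genes, 311 higher and 425 lower, of which 243 differed by at least 2-fold, and 3761 genes had an unadjusted p under 0.05 against 895 by chance. Arntl had an adjusted p = 5.2e-05 (log2 -2.13, SE 0.18), Hspa1a 0.013 (2.32, SE 0.41), Cldn8 0.0085 (-1.4, SE 0.22) and Ocln 0.013 (-0.59, SE 0.1). Other large rises were Abca12, a lipid transporter gene (11.5-fold), the keratin gene Krt12 (8.45-fold) and the actin gene Acta1 (5.79-fold). Large falls were those of the transcription factor genes Tcf23 (9.1-fold) and Prdm14 (5.47-fold), the phosphate transporter gene Slc34a2 (3.86-fold), the sialidase gene Neu3 (3.86-fold), Apoc2 (3.85-fold) and Gal3st2c (4.54-fold). Pdzd7 fell 16.1-fold, from 3.07 ± 2.77 to 0.188 ± 0.123 CPM, although 2 naive libraries lay near the values of the KC84 group. Slc9a3, a sodium-hydrogen exchanger, rose 2.24-fold, from 294 ± 152 to 657 ± 109 CPM. Of 36 called genes followed through the 14 fits that left out 1 library, 24 lost the call in at least 1: Mx1 in 12, Gal3st2c in 11, Abca12 and Slc9a3 in 10, Acta1 and Pdzd7 in 9, Neu3 in 8, Tcf23 and Ccnb2 in 7, Krt12, Cd14 and Hsd11b2 in 6, Apoc2 in 5, Chac1, Slc34a2, Bub1, Saa3, Per1 and Zbtb16 in 4, Cldn12 in 3, Dnajb9 in 2 and Prdm14, Ddc and Hsph1 in 1. On TPM 13 of the 36 lost it, among them Ddc and Bub1, and 2 lost it with the replicate number as a block and 1 without both replicate 5 libraries. Abca12 went from log2 3.52 to 5.25 without naive replicate 4, and Krt12 from 3.08 to 2.4 without 5-HTP+KC84 replicate 3. DESeq2 called 1832 genes and voom 3503. The count was 225, 264, 1165 and 478 without naive replicates 2, 3, 4 and 5, and 375, 228, 105 and 418 without 5-HTP+KC84 replicates 1 to 4. It was 2734 without both replicate 5 libraries and 460 on TPM.

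By list, 10 clock genes rose and 3 fell over all genes, and 11 rose and 5 fell adjusted over the list alone (camera adjusted p = 9.39e-05, with adjusted p = 0.054 with an estimated correlation). Of 12 heat shock genes 5 rose over all genes and 10 adjusted over the list alone (median 0.68, adjusted p = 5.57e-08), with adjusted p = 0.38 with an estimated correlation. Of 16 endoplasmic reticulum stress genes 3 rose, and 8 adjusted over the list alone (median 0.63, 4.65e-06), with adjusted p = 0.38 with an estimated correlation. Junction genes fell in 5 and rose in 1 of 18, with 6 and 1 adjusted over the list alone (median -0.27, 0.000542), with adjusted p = 0.33 with an estimated correlation. Proliferation genes fell in 2 of 20, Bub1 and Ccnb2, and in 12 adjusted over the list alone (median -0.51, 4.65e-06), with adjusted p = 0.62 with an estimated correlation, and these 2 calls were lost in 4 and 7 of the 14 fits that left out 1 library. The proliferation score of 5-HTP+KC84 replicate 4, at 0.284, lay above every naive library (0.015 to 0.15) except naive replicate 1, which stood apart at 0.518. The other libraries with KC84 lay at -0.454 to -0.384 (exact permutation p = 0.0794 between the groups). Markers of enteric neurons (median 0.58, 4.65e-06) and smooth muscle (0.41, 0.00816) stood higher, and those of macrophages (-0.35, 0.000542), T and NK cells (-0.59, 0.00587) and class II presentation (-0.39, 0.0287) stood lower. With an estimated correlation these had adjusted p = 0.38, 0.69, 0.38, 0.69 and 0.69, and class II presentation had 0.0662 without both replicate 5 libraries. The T and NK cell score of naive replicate 3 stood apart at 1.1, with the other naive libraries at 0.02 to 0.28. Posterior Hox genes, which mark position along the colon, were negative in 7 of 9 (median -0.39, camera adjusted p = 0.0923, permutation p = 0.0159, or 0.093 adjusted), with adjusted p = 0.38 with an estimated correlation and with 0 called by edgeR, 4 lower adjusted over the list alone, 5 at an unadjusted p under 0.05, 4 lower by DESeq2, and 4 lower and 1 higher by voom. Hoxb13 averaged 105 ± 24.5 against 275 ± 70.1 CPM and was below every naive library in 4 of 4 (log2 -1.39, SE 0.42, adjusted p = 0.072, or 0.0074 to 0.2 with 1 library left out). Interferon-stimulated genes had a median of 0.06 (adjusted p = 0.303), and Mx1 alone among them rose, 3.53-fold to 16 ± 8.38 CPM (adjusted p = 0.046), a call that was lost in 12 of the 14 fits that left out 1 library. Adjusted over the list alone, 0 of these genes passed. Mx1 ran from 1.83 to 14.1 CPM within the 5-HTP group, and whether an inherited variant sets its level in these outbred mice was not tested. Of 41 lists 11 were called, 6 higher and 5 lower, fry called 6, and 0 were called with an estimated correlation or by the permutation test, in which 12 had an unadjusted p under 0.05.

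Of the 17 genes called with KC84 against 5-HTP, 12 also rose and 4 also fell against naive colon, in comparisons that share the KC84 libraries and so overlap in part for that reason alone. Across genes, 5-HTP and 5-HTP+KC84, each against the same naive libraries, correlated at 0.767, against 0.496 (0.139 to 0.746) for simulated unchanged groups. The covariance was 0.1282 against 0.0386 simulated, and the correlation averaged 0.434 when the naive libraries were split between the comparisons.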

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

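Of the tests in this part, the time of day, cell mixture, RNA integrity and transcript length bias tests and the position test for exchanged labels were chosen only after results were seen. Libraries far from the rest of their group were sought with a Dixon test on 309 groups of values, from 79 genes and 24 lists, and 22 were found where chance alone flags about 1 in 20 groups, 15 here.

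Naive replicate 4 lay lowest of its group for Slc6a4 (log2 CPM 3.22, others 4.15 to 4.39), Cldn2 (6.54, others 7.05 to 7.23), Hoxb13 (7.3, others 8.15 to 8.43) and Neu3 (1.92, others 3.51 to 4.08), and highest for Prph (3.94, others 3.16 to 3.35) and for the xenobiotic metabolism score (0.14, others -0.39 to -0.28). 5-HTP replicate 5 lay lowest for Tjp1 (6.3, others 7.49 to 7.54), Per2 (3.81, others 4.47 to 4.55), Bub1 (3.64, others 3.98 to 4.07), Gal3st2c (1.33, others 3.55 to 4.43) and Zbtb16 (5.51, others 5.9 to 6), and highest for Krt12 (3.19, others 0.43 to 1.02). 5-HTP replicate 1 lay lowest for Mx1 (0.9, others 3.25 to 3.82). 5-HTP+KC84 replicate 1 lay lowest for Acta1 (2.45, others 4.46 to 4.59), Slc9a3 (8.95, others 9.44 to 9.5) and the score of serotonin synthesis, transport and breakdown (-0.12, others 0.12 to 0.14). 5-HTP+KC84 replicate 4 lay lowest for Per2 (5.28, others 5.74 to 5.79) and highest for the proliferation score (0.28, others -0.45 to -0.38). Naive replicate 2 lay highest for Tef (4.84, others 3.95 to 4.2) and lowest for the score of glucocorticoid-responsive and local steroid genes (-0.16, others -0.04 to 0). Naive replicate 1 lay highest for the proliferation score (0.52, others 0.01 to 0.15) and naive replicate 3 for the T and NK cell score (1.1, others 0.02 to 0.28).

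Clock genes differed between groups in the manner of a shift along the daily cycle. The arm of Arntl and its partners was lower with KC84 than with 5-HTP (median log2 -1.17, 5 of 5 genes), while the Per and Dbp arm was higher (median 1.5, 10 of 10). The mean of the Per and Dbp arm had an SE of 0.23, taken across its genes. These are not independent replicates, so that SE holds no spread between libraries. Among libraries of the same group the arms also moved against each other, with a Pearson r of -0.85 over 14 libraries (permutation p = 0.00034, Spearman -0.82 at p = 0.0018, Pearson -0.84 without the 2 farthest), so differing collection times could account for the pattern. None of the 18 cell type lists shifted as far, the largest absolute median being 0.53, for neutrophils and eosinophils. A change in the mixture of the listed cell types was therefore too small to account for the pattern, while cell types without a list were not tested. Length bias of the replicate 5 libraries did not account for it, since the Per and Dbp arm had a median of 1.71 without them (SE of the mean across genes 0.26). Collection at different times and a treatment that moves the clock itself would leave the same mark, and the data cannot separate them without recorded times.

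The higher score of interferon-stimulated genes with KC84 than with 5-HTP, 0.82 (SE 0.37), stayed at 0.85 (SE 0.37) with the mean of the T and B cell scores as covariate. By the rule set beforehand, lymphoid cell content read from those scores did not account for it. By the stricter rule given below for the replicate 5 libraries, this would stay open, since 0.85 is not above 0.5 of the difference by 2 SE. No score of other cells was used as covariate. Whether position in the daily cycle could was left open, with a Pearson r of -0.06 within groups over 14 libraries (permutation p = 0.84, Spearman -0.01 at p = 0.99, Pearson 0.03 without the 2 farthest, interval -0.62 to 0.54). Without both replicate 5 libraries the difference was 0.93 (SE 0.41, exact permutation p = 0.0286), so their length bias did not account for it as a whole, read by the same rule as lymphoid cell content, which was applied here after the value was seen; by the stricter rule first set, above 0.5 of the difference by 2 SE, it would stay open.

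The naive and 5-HTP libraries also split on something other than their groups. The posterior Hox score, a sign of position along the colon, was read here after results were seen. Naive replicate 4 scored lowest of its group (-0.014, others 0.147 to 0.672). 5-HTP replicate 1 scored highest of its group (0.192, others -0.389 to -0.152). Whether the part of the colon taken differed between libraries, or accounts for this split or for group differences, was not tested. Deviations of both replicate 5 libraries fell with transcript length, the weaker correlation across genes being -0.43 against -0.18 to 0.31 in the other 12 libraries, which fits lower RNA integrity, and the deviation they shared correlated at 0.47 and at 0.27 once length and GC trends were removed, which leaves open whether length was the whole of it. The deposited labels separated 533 genes without overlap and exchanging naive replicate 4 with 5-HTP replicate 1 separated 915, against at most 569 (median 133.5) in the 24 other arrangements near the exchanged one and 142 expected by chance. On genes separated in the other 8 libraries, where 0 is naive and 1 is 5-HTP, naive replicate 4 lay at 0.62 and 5-HTP replicate 1 at 0.45. In pairs that left out neither of these, and so kept both among the references, other naive libraries lay at -0.02 to 0.61 and other 5-HTP libraries at 0.4 to 1.16. These ranges overlap only through pairs that left out a replicate 5 library. Without such pairs they were -0.02 to 0.39 and 0.76 to 0.93. Naive replicate 4 and 5-HTP replicate 1 lay between these and matched neither, so their positions do not decide on an exchange. By the rule set beforehand, 533 reads as an exchange of labels because it does not exceed 569. Under an exchange, however, the deposited labels would be 1 more such arrangement, and 533 lies far above the median of 133.5. The count therefore cannot decide, and the explanation came from these same data. Read after results were seen, the posterior Hox score ran against the deposited labels. The Per and Dbp clock arm ran with them, naive replicate 4 being lowest of its group (-0.99) and 5-HTP replicate 1 highest of its group (0.11). All results keep the deposited labels.

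The gene tests were repeated on 100 of the 126 ways to divide the libraries of each comparison at random into groups of the same sizes, the real grouping being 1 of the 100 and counted among them. For 5-HTP against naive, 3 splits gave as many called genes as the 2 found, the highest being 396, which came from the split that exchanged naive replicate 4 and 5-HTP replicate 1 and so shows structure among the samples. For 5-HTP+KC84 against 5-HTP, 2 splits gave as many as the 17 found, the highest being 80, which came from the split that exchanged 5-HTP+KC84 replicate 4 and 5-HTP replicate 5, and for 5-HTP+KC84 against naive, only 1 split, the real one, gave 736, the highest other being 24. Counts of called lists were no larger than random splits give: 11 of 100 splits reached the 17 found for 5-HTP against naive (highest 20), 20 reached the 13 found for 5-HTP+KC84 against 5-HTP (highest 18), and 49 reached the 11 found for 5-HTP+KC84 against naive (highest 21). The number of lists called by camera therefore could come from sample structure alone.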

How the results depend on the processing

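The fit without both replicate 5 libraries and the exact permutation of list scores were chosen only after results were seen. Of the genes followed through 7 alternatives and the fits that left out 1 library, those that passed the test in any fit kept their sign, while uncalled genes with small differences changed sign, such as Tph1 for 5-HTP against naive (-0.23 to 0.09 with 1 library left out). The genes named for being moved back were not followed in this way. Scaling with RLE or upper-quartile factors shifted median fold changes by at most 0.027. RLE factors and the absence of a low-count filter left each gene count within 1.5 times its value.

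For 5-HTP against naive, the 2 called genes became 1 with upper-quartile factors, 1 with an absolute log2 fold change of at least 1 added, 32 without both replicate 5 libraries, 147 with 1 surrogate variable, 545 with DESeq2 and 868 with voom and quality weights. Leaving out 1 library gave from 0 (without naive replicate 2 or 3) to 242 (without naive replicate 4). Bhlha15 kept its direction and its call in all 7 other settings, with adjusted p from 4.5e-13 to 0.028, and Slc6a4 had adjusted p from 0.012 to 0.22 there.

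For 5-HTP+KC84 against 5-HTP, the 17 called genes became 64 with DESeq2, 140 with voom, 5 with only the groups compared, 11 on TPM with a pseudocount of 1, 11 with 0.1, 33 with 1 surrogate variable and 38 without both replicate 5 libraries, and leaving out 1 library gave from 3 (without 5-HTP replicate 2 or 4) to 30 (without 5-HTP replicate 5). Arntl, Ciart and Per3 passed in all 14 fits that left out 1 library and in 7 other settings, with a highest adjusted p of 0.0063, 0.007 and 0.007 when 1 library was left out. Npas2 lost its call in 7 of 14 such fits, with an adjusted p of up to 0.13.

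For 5-HTP+KC84 against naive, the 736 called genes became 1832 with DESeq2, 3503 with voom, 460 on TPM with a pseudocount of 1, 461 with 0.1, 2531 with 1 surrogate variable, 2734 without both replicate 5 libraries and 243 with an absolute log2 fold change of at least 1 added. Leaving out 1 library gave from 105 (without 5-HTP+KC84 replicate 3) to 1165 (without naive replicate 4).

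The 17, 13 and 11 called lists became 0, 1 and 0 with an estimated correlation, 0, 1 and 6 with fry and 0, 0 and 0 by exact permutation of the list score per library, for 5-HTP against naive, 5-HTP+KC84 against 5-HTP and 5-HTP+KC84 against naive. The permutation p cannot fall below 0.00794. The clock list reached that floor for 5-HTP+KC84 against 5-HTP and still had 0.33 adjusted. The permutation counts of 0 therefore do not by themselves weigh against a list. That floor does not account for an unadjusted permutation p above 0.05, which other lists called by camera had. For 5-HTP against naive these included interferon-stimulated genes (0.143) and T and NK cells (0.167). For 5-HTP+KC84 against 5-HTP they included proliferation (0.183) and heat shock genes (0.198). Of all tested lists, 8, 3 and 12 had an unadjusted permutation p under 0.05, in the order above. Without both replicate 5 libraries, xenobiotic metabolism had an adjusted p of 0.127 for 5-HTP against naive. Leaving out 1 library gave 12 to 19, 7 (without 5-HTP replicate 1) to 13 and 10 to 16. The 0 genes moved back became 3 with DESeq2 and 1 (Gm6212) without 5-HTP+KC84 replicate 4, and stayed 0 in every other fit that left out 1 library. Fits with fewer libraries have less power by construction; for the other changes the cause was not tested.

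The labels give the groups the same replicate numbers. As a replicate block these gave 217, 21 and 2326 genes, 14, 11 and 12 lists and 0 genes moved back. Deviations of libraries with the same number correlated at only -0.144 to 0.447 across genes, which are not independent replicates, and 5 of 14 libraries matched their own number best, so the numbers were not used as pairs. The gain with the block may rest on the replicate 5 libraries, whose correlation of 0.447 was the highest, but the cause was not tested.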

Other observations

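The lists of this part were fixed before the data were seen, but which of them to describe was chosen only after results were seen. With 5-HTP, Saa3, an acute-phase protein of the epithelium, averaged 1.55 ± 0.85 against 0.286 ± 0.252 CPM (SD, n = 5 each, adjusted p = 0.089), Sprr1a, an antimicrobial protein, 26.4 ± 34.9 against 3.77 ± 1.9 CPM (0.12) and Nos2, which makes nitric oxide, 7.93 ± 6.64 against 1.2 ± 0.902 CPM (0.18), while Lyz1, a lysozyme, was lower at 13.6 ± 4.98 against 28.4 ± 8.5 CPM (0.16). The Sprr1a mean rests on 5-HTP replicate 5, at 88.5 CPM, and its log2 difference of 2.8 was 1.51 without that library, that of Saa3 was 3.12 in place of 2.44 without naive replicate 5, and that of Nos2 was 3.38 in place of 2.72 without both replicate 5 libraries. The list of antimicrobial and microbe-responsive epithelium had a median log2 of 0.47 (camera adjusted p = 0.0462), with adjusted p = 0.56 with an estimated correlation. By edgeR 0 of its 17 genes passed over all genes, against 5 adjusted over the list alone, 7 at an unadjusted p under 0.05, 4 by DESeq2 and 3 by voom. With KC84, Saa3 was called above naive colon, 5.65-fold at 1.62 ± 0.479 CPM (edgeR adjusted p = 0.023, log2 2.5, or 3.18 without naive replicate 5), a call lost in 4 of the 14 fits that left out 1 library.

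Tuft cell genes were positive in 11 of 11 with 5-HTP (median 0.28, camera adjusted p = 0.0147), with adjusted p = 0.56 with an estimated correlation, in 10 of 11 with KC84 against 5-HTP (0.27, 0.0164), with adjusted p = 0.68 with an estimated correlation, and in 11 of 11 with KC84 against naive (0.59, 0.000557), with adjusted p = 0.54 with an estimated correlation. Xenobiotic metabolism genes had a median of 0.21 with 5-HTP (0.0231) and inflammatory cytokine genes 0.15 (0.0464), both with adjusted p = 0.56 with an estimated correlation, and cholesterol synthesis genes -0.19 (0.01), with adjusted p = 0.58 with an estimated correlation. With KC84 against 5-HTP, cholesterol synthesis genes had a median of 0.12 (0.0159), with adjusted p = 0.71 with an estimated correlation, and haemoglobin genes -0.5 (0.0147), with adjusted p = 0.67 with an estimated correlation. Without both replicate 5 libraries these had adjusted p = 0.162 and 0.214, and tuft cell genes 0.203.

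Glucocorticoid-responsive and local steroid genes had a median of 0.09 with KC84 against 5-HTP (camera adjusted p = 0.029), with adjusted p = 0.49 with an estimated correlation and, without both replicate 5 libraries, a median of 0.2 at 0.11. By edgeR, 4 of the 15 rose and 1 fell with KC84 against naive colon, and the same numbers passed adjusted over the list alone, while the list had a median of 0 with 7 genes positive and 8 negative, at a camera adjusted p = 0.303, with adjusted p = 0.69 with an estimated correlation. Per1, also a clock gene, rose 1.9-fold to 46 ± 6 CPM (adjusted p = 0.026), Zbtb16, a transcription factor, rose 1.73-fold to 57.1 ± 10 CPM (0.028) and Hsd11b2, which inactivates glucocorticoids, fell 1.65-fold to 157 ± 18.9 CPM (0.032), calls lost in 4, 4 and 6 of the 14 fits that left out 1 library. Fabp7, a fatty acid binding protein of enteric glia, fell 2.95-fold with KC84 against 5-HTP, from 0.688 ± 0.178 to 0.23 ± 0.0228 CPM (0.032), a call lost in 11 of those fits. It was also lost in 2 of 7 other settings, at an adjusted p of up to 0.063.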
